A study of Mus musculus with 6 samples.

How the data were processed

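Gene expression was measured in lineage-negative, Kit-positive (LK) cells, the fraction of mouse bone marrow that holds blood stem and progenitor cells, sorted by flow cytometry. The mice were NHD13 transgenics or their wild type littermates at 3 months of age. NHD13 is the usual name of a transgene that encodes the NUP98-HOXD13 fusion, found in human leukaemia and myelodysplastic syndrome. Per the labels' protocols, total RNA was extracted with Trizol from marrow pooled from 3 mice, reverse transcribed from an oligo(dT) primer and transcribed in vitro with biotin-labelled nucleotides. Each of the 6 arrays, 3 per genotype, thus stands for 3 mice.

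The deposited table of bead array data gives, per the file headers, each probe's average intensity, its number of beads, the standard error over beads and a detection p-value. The intensity values were neither background-subtracted nor normalized: the array medians differed, and no value lay below 91.0. The deposited p-values fell in steps of 1 in 936, which gives the number of negative control probes behind them. A second deposited table holds the authors' processed values of the same arrays. These were linear intensity values with a common distribution on all arrays, medians of 10.4 and a lowest value of -45.6, so background had been subtracted and the arrays brought to one distribution. The ranks of the probes on each array equalled those of the first table (Spearman's rho of 1 across probes). The software and settings of the scanner are not given in the sources used here. Each column name gave its genotype and number.

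The first table was normalized with the neqc method of limma 3.58.1 in R 4.3.3: normexp background correction with negative controls inferred from the detection p-values, an offset of 16, quantile normalization and log2. Probes with a detection p-value under 0.05 on at least 3 of the 6 arrays were tested, which kept 16518 of 45281. Each probe was tested two-sided with lmFit and eBayes, and p-values were adjusted over all tested probes by the Benjamini-Hochberg method at 0.05. A gene was represented by its tested probe with the highest mean over all arrays, and no gene's level was set against another gene's. Gene symbols came from the platform annotation, in which 34885 probes had 1 symbol, 18 had several and 10378 had none. Gene IDs of 34807 probes were found in the RefSeq gene table of assembly GRCm38.p6, which changed 0 symbols. Of the tested probes, 13933 had 1 symbol, for 9000 genes.

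Where a gene was below background on all 3 arrays of a group, its difference is given as at least N-fold. This bound sets the bright group's mean log2 value against the dim group's mean of, per array, the lowest normalized value of a detected probe or the dim probe's own value if higher. A bound holds for the main normalization alone, and bounds without 1 array use the same normalized values. Such floors lay between 5.39 and 5.49 on the 6 arrays.

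Before the data were examined, 25 gene lists, the tests and the alternatives were fixed. The lists cover Hox genes, Hox cofactors, the BCL2 family, p53 targets, blood lineages, cell types the sort could let through, the cell cycle, DNA repair, stress, metabolism, ribosomal proteins and sex-linked genes. All but the sex-linked list were tested as sets, 24 in all, with limma's camera on 1 probe per gene at a preset correlation of 0.01. Camera with an estimated correlation and fry were run beside it, and p-values were adjusted over the lists. The rule for named genes, also fixed then, took Hoxd13, Nup98 and Kit, and the 10 genes with the largest rise and the 10 with the largest fall among called genes whose groups did not overlap, leaving out predicted symbols. From each list it took up to 4 called members of smallest p, or up to 2 members where none was called, as values. Hoxa2, Hoxa4, Hoxb4, Slamf1, Gata1, Tfrc, Elane, Gapdh, Ldha, Eif2s3y and the genes passing over the stem cell list alone were named beyond this rule, after their values were seen.

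The labels give both genotypes the numbers 1 to 3 without saying what a number shares. Deviations from the group means correlated across probes at 0.19, 0.67 and 0.54 between the arrays numbered 1, 2 and 3, and 5 of the 6 arrays correlated best with the array of their own number. Arrays of different number and genotype correlated between -0.61 and 0.24. By a rule fixed beforehand, correlations over 0.1 in every pair were to be read as pairing, so a fit with the replicate number as a block was run as an alternative. The 0.19 of the arrays numbered 1 lay under the 0.24 reached between arrays of different number. The rule therefore does not settle whether the numbers pair the samples, and the main fit left them out. The other alternatives were no background correction, median scaling, the authors' processed values, 2 other detection filters, an intensity trend with robust variance, array weights, an offset of 50, other rules for genes with several probes, a 1.2-fold minimum, a plain equal-variance test and leaving out each array. An alternative without both arrays numbered 2 was added after the data were seen.

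The steps were tested on simulated log2 values for the 16518 probes in 2 groups of 3 arrays, with 200 probes changed in each of 20 simulations. Changes of 1, 2, 3 and 4 on the log2 scale were found in 21.2%, 83.6%, 93.7% and 98.5% of cases, and 4.65% of calls were false. A list moved by 1 was called in 100% of simulations and an unmoved list in 0%, at an unadjusted p under 0.05. The simulated probes varied independently, whereas the estimated correlation within the real lists reached 0.86, for granulocyte-monocyte progenitor genes. The simulation therefore does not test list calls among correlated genes. Each simulated probe's variance was drawn from the distribution of variances that limma had fitted to these data, with normal noise. A false share near the threshold was thus built in, and it is no error rate of the genes called in the real data. Precision is limited by the number of arrays. The figures were drawn with matplotlib 3.10.9.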

Results

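RNA from sorted LK bone marrow cells was hybridised to 6 bead arrays, 3 from NHD13 transgenic mice and 3 from wild type littermates, each array holding a pool of 3 mice. The arrays detected between 15983 and 16836 of 45281 probes, with a median of 42 or 43 beads per probe. Normalized log2 values correlated across probes at 0.94 to 0.98 between arrays of one genotype and at 0.92 to 0.98 between genotypes. No array was a copy of another: 34.0% to 55.3% of probes differed between arrays of one genotype by more than 2 bead standard errors. NHD13 replicate 2 stood farthest from the rest on the first principal component, which held 59.1% of the variance. The comparison asks which genes the transgene's carriers express differently in their stem and progenitor cells.

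Genes of all 4 Hox clusters, which encode transcription factors of body patterning and blood cell growth, were higher in NHD13 cells, among them Hoxc6, Hoxb7 and Hoxb5. Pbx3, a Hox cofactor, and Eya1, a transcriptional coactivator, rose with them. Among the genes that fell were Fkbp9, Gspt2, Rps4l, Tceal8 and Ppic. Of 9000 genes tested, 50 passed the adjusted threshold, 18 higher and 32 lower. On the probe level, 67 passed, 25 higher and 42 lower, of which 7 had no gene name. In all 50 genes the 3 NHD13 values lay outside the range of the 3 wild type values, as in 12.5% of all tested genes, where chance gives 10%. Without background correction 24 genes passed, 54.2% rather than 36% of them higher. Array weights, which among NHD13 arrays rest mostly on replicate 1, gave 342 genes. The plain equal-variance test gave 0, with 662 genes at an unadjusted p under 0.05 against 690 in limma. The count was 1 without wild type replicate 1, 4 without wild type replicate 3, 16 without NHD13 replicate 1 and 24 without wild type replicate 2, and without both arrays numbered 2, an alternative chosen after the data were seen, it was 16.

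The genes behind the transgene and the sort did not pass. Nup98, the nucleoporin gene of the fusion, measured 8.05 ± 0.19 in NHD13 and 7.95 ± 0.24 in wild type cells (log2, SD, n = 3 pools; adjusted p = 0.88). Kit, the receptor used for sorting, measured 12.60 ± 0.26 and 12.82 ± 0.18 (adjusted p = 0.78). The mouse Hoxd13 probe was detected on 1 wild type and 0 NHD13 arrays and was not tested. A mouse probe need not read the transgene, so these values check nothing about the labels.

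Among 18 tested Hox genes, 8 rose and 0 fell, and 12 rose when adjusted over the list alone, among them Hoxa2, of which a dimmer probe passed over all probes (at least 2.63-fold higher, adjusted p = 0.022). Hoxc6 was at least 45.9-fold higher in NHD13 cells (10.94 ± 0.77 log2, SD, n = 3, adjusted p = 0.0036), since its probe was below background on all wild type arrays. The same held for Hoxb7 (at least 8.30-fold), Hoxb5 (at least 6.85-fold), Hoxd8 (at least 2.89-fold) and Hoxb6 (at least 2.81-fold). The bound of Hoxc6 was 34.4-fold without NHD13 replicate 3 and 58.2-fold without NHD13 replicate 2. Across the alternatives that tested them, the log2 difference ranged from 3.69 to 6.45 for Hoxc6 and from 1.71 to 4.39 for Hoxb7. The bounds are thus no lower limits over the alternatives. Hoxa5, Hoxa7 and Hoxa9 of the A cluster were measured in both genotypes and rose by 2.59 ± 0.29, 1.95 ± 0.16 and 2.05 ± 0.20 in log2 (SE, n = 3 against 3). Hoxa7 and Hoxa9 were named after their values were seen. Hoxb4, the cluster member tied to stem cell self-renewal, measured -0.02, and Hoxa4 measured 0.55, and neither passed. The list's median difference was 1.77, or 1.45 with genes below background at their bounds (camera adjusted p = 1.3e-20). With an estimated correlation the adjusted p was 0.012, and 0.36 with the replicate block added. Without wild type replicate 1 none of the 8 genes passed and without wild type replicate 3 only 2 did, though all 8 were still higher, and without background correction the list's median was 0.65 and without a detection filter 0.27. Members undetected in wild type, such as Hoxc6 and Hoxb7, passed the filter only through the NHD13 arrays. The median of 1.77 is thus that of a set partly selected by its level in NHD13.

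**Figure D1:**
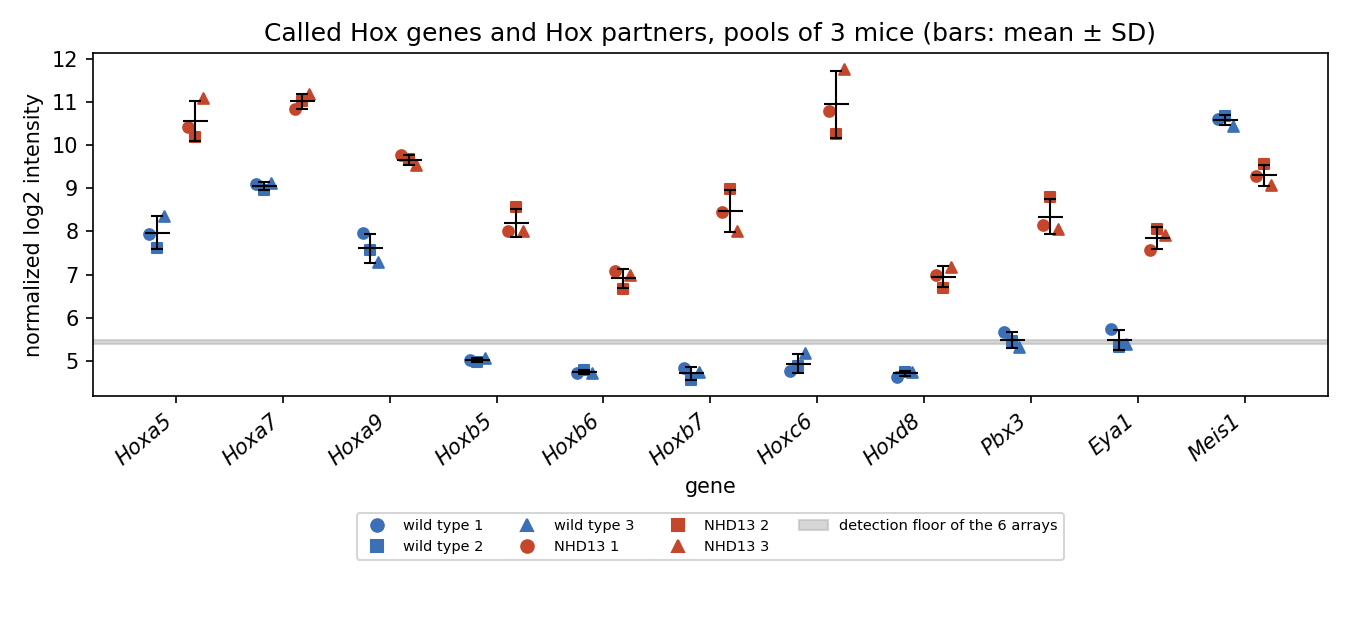
Normalized log2 intensity (vertical axis) of the 8 called Hox genes and of Pbx3, Eya1 and Meis1 (horizontal axis) on each array, with wild type in blue, NHD13 in red, a marker shape per replicate number, and black bars for mean and SD of 3 arrays. The grey band spans the detection floors of the 6 arrays, 5.39 to 5.49, the wild type values of Hoxb5, Hoxb6, Hoxb7, Hoxc6 and Hoxd8 lie under it, and Meis1 is the single gene shown that was lower in NHD13.

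Hox cofactors and leukaemia-linked regulators moved both ways. Pbx3 rose 7.21-fold (2.85 ± 0.24 log2, SE, adjusted p = 0.0075), detected on 2 of 3 wild type arrays, and Eya1 rose from detection on 1 of 3 wild type arrays to 3 of 3 NHD13 arrays (adjusted p = 0.0076). Meis1, which binds DNA together with Hox and Pbx proteins, fell 2.42-fold (-1.27 ± 0.18, adjusted p = 0.048), and the list's other 11 tested members did not pass. Adjusted over the list alone, 3 rose, Prdm16 being the third, and 1 fell. The median of the list was -0.08, its mean was 0.24, and camera called no shift (adjusted p = 0.62). With detection on all 6 arrays required, which leaves fewer members and drops the risen Pbx3 and Eya1, the list was called lower (median -0.20, adjusted p = 0.019). Fry's mixed test, which counts changes in either direction, gave an adjusted p of 7.6e-05. The 3 probes of Meis1 differed by -1.65 to -0.10 and the lowest of the 3 of Eya1 by 0.15. Meis1 passed in 5 of 17 alternatives, always below 0.

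Other genes that rose were Igf2bp3, an RNA-binding protein of fetal blood cells (at least 5.70-fold), Zfpm2, a cofactor of GATA proteins (at least 5.40-fold), and Hdac9, a histone deacetylase (at least 5.22-fold). The probes that give these bounds were below background on the 3 wild type arrays. Igf2bp3 did not pass with the replicate block (adjusted p = 0.047 without it and 0.058 with it). It passed in 5 of 16 alternatives that tested it. For Igf2bp3 and Zfpm2, 1 dimmer probe each differed by -0.05 and -0.01, so the rise was not seen by every probe. The last 5 called genes that were higher, named after their values were seen, were Ttc39a, Aard, Gjb2, Liph and Xlr4a.

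The genes that fell included Fkbp9 and Ppic, which belong to the prolyl isomerase families, and Gspt2, a translation termination factor. Fkbp9 was at least 7.48-fold lower (8.35 ± 0.19 log2 in wild type, SD, n = 3, adjusted p = 0.0022), below background on all NHD13 arrays. It was the gene that passed without wild type replicate 1. Its log2 difference ranged from -4.15 to -1.58 over the alternatives that tested it. Gspt2 fell to detection on 1 of 3 NHD13 arrays, with their mean under the detection floor (adjusted p = 0.049), and Ppic fell 6.27-fold (adjusted p = 0.020). Rps4l was at least 5.81-fold lower, and Tceal8 and Bex4, neighbours on the X chromosome, fell 7.99-fold and 6.02-fold. Bex4 did not pass with the replicate block (adjusted p = 0.099) and passed in 7 of 17 alternatives, Gspt2 and Nkx2-3 in 7 of 16 each and Ryk in 8 of 17. Ryk, a Wnt receptor, fell 5.58-fold, Nkx2-3, a homeobox gene, fell likewise to detection on 1 of 3 NHD13 arrays (adjusted p = 0.035), and Uaca was at least 3.54-fold lower. Smo, the transducer of Hedgehog signals, fell by 2.09 in log2 and Mmp2, a matrix protease, was at least 1.81-fold lower; both were named after their values were seen. Of the 50 called genes, 15 were below background on all NHD13 arrays and 9 on all wild type arrays.

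**Figure D2:**
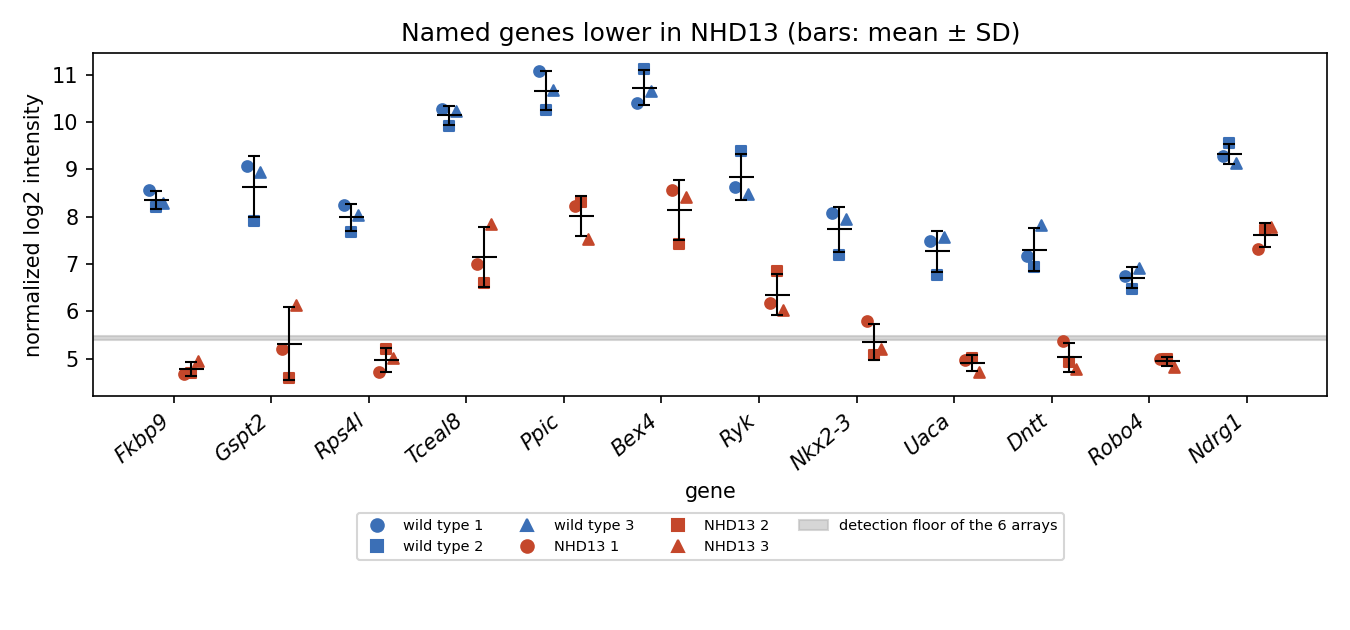
Normalized log2 intensity (vertical axis) of 12 named genes that were lower in NHD13 (horizontal axis), with wild type in blue, NHD13 in red, a marker shape per replicate number, and black bars for mean and SD of 3 arrays. The grey band spans the detection floors, 5.39 to 5.49, all 3 NHD13 values of Fkbp9, Rps4l, Uaca, Dntt and Robo4 lie under it, and the 2 genotypes do not overlap in any of the genes.

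Among 23 tested genes of stem cells and multipotent progenitors, Robo4 and Nkx2-3 fell and Hoxb5 rose. Robo4, a guidance receptor of stem cells and endothelium, was at least 2.40-fold lower (adjusted p = 0.013). Adjusted over the list alone, 9 members fell, among them Cd34 (-1.73), Emcn (at least 1.72-fold lower) and Tie1 (at least 1.40-fold lower), and Esam and Tek, detected on 1 and 2 of 3 NHD13 arrays, and 2 rose, Hoxb5 and Prdm16. Other members of the same list lay above 0 without passing, such as Slamf1 at 0.88. The list's median was -0.26 (camera adjusted p = 0.0039; adjusted p = 0.46 with an estimated correlation). With array weights the median was -0.36 with an adjusted p of 0.065. With detection on all 6 arrays required, it was 0.02 and the call was lost. That filter drops Robo4, Nkx2-3, Emcn, Tie1, Esam and Tek, which fell, and Hoxb5, which rose, as undetected on some arrays. It therefore cannot test these changes. Without a detection filter the median was -0.05, still called.

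Erythroid genes rose as a list, with 23 of 26 tested members above 0 and a median of 0.44, though none passed by itself (camera adjusted p = 0.00046; adjusted p = 0.57 with an estimated correlation). Cpox, an enzyme of haem synthesis, measured 1.08 ± 0.37 in log2 (SE, n = 3 against 3, adjusted p = 0.54), Tspan33 measured 0.54 ± 0.20, and the regulator Gata1 measured 0.82. Genes of haem synthesis and iron handling rose likewise, 18 of 20 above 0 with a median of 0.36 (camera adjusted p = 0.00046; adjusted p = 0.57 with an estimated correlation), and 4 of them, such as Cpox and Tfrc, also stand in the erythroid list. Tfr2, an iron sensor, measured 0.78 (adjusted p = 0.60). Erythroid list means differed between the arrays of one number by 0.78, 0.23 and 0.09. With array weights the median was 0.72 for erythroid and 0.62 for haem genes. These weights were 5.02 for NHD13 replicate 1, whose pair differed by the 0.78, and 0.55 and 0.35 for NHD13 replicates 2 and 3. The haem median was 0.55 without NHD13 replicate 3. Megakaryocyte genes were not called over 16 members (median 0.01, mean -0.08, camera adjusted p = 0.62), and their median was -0.28 without NHD13 replicate 2, 0.37 without wild type replicate 2 and 0.35 without NHD13 replicate 3. In that list the platelet protein gene Mmrn1 was below background on all NHD13 arrays, at least 2.42-fold lower (adjusted p = 0.17), and passed over the list alone, while Selp measured 0.86.

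**Figure D3:**
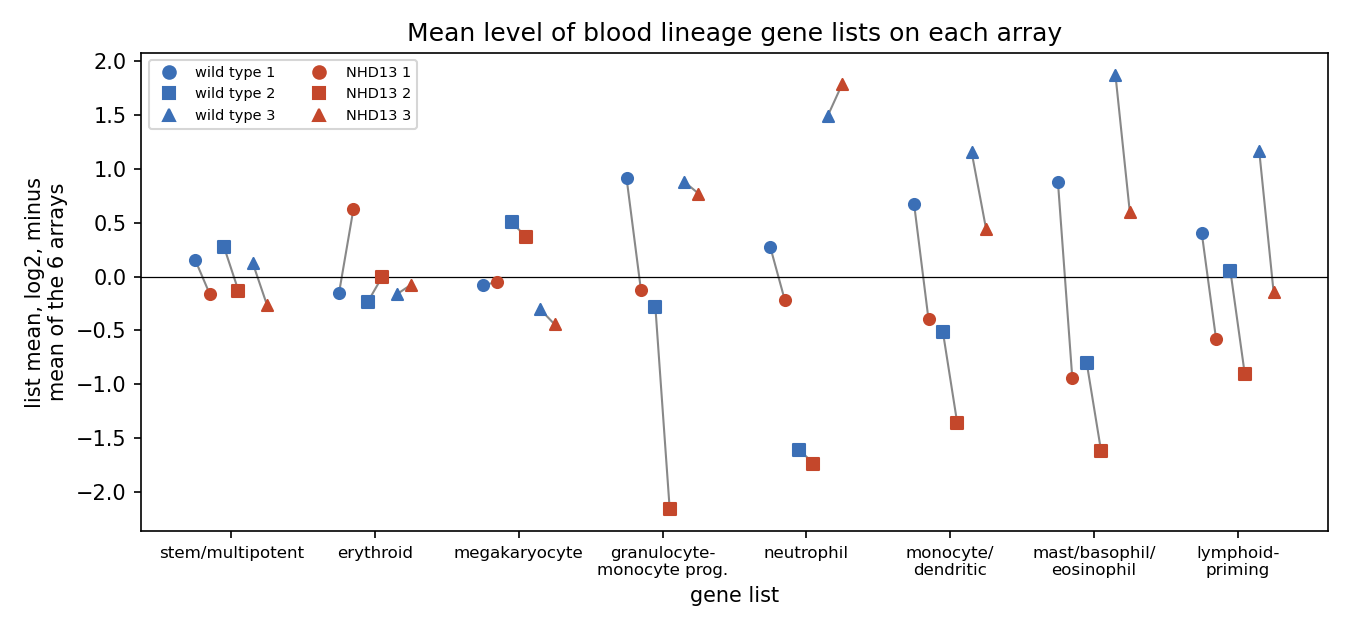
Mean log2 level of 8 gene lists of blood lineages (horizontal axis) on each array, minus the mean of the 6 arrays (vertical axis), with wild type in blue, NHD13 in red and grey lines joining arrays of one number. In the granulocyte-monocyte progenitor list the NHD13 array lies under its wild type partner by 1.04, 1.88 and 0.11, and both arrays numbered 2 lie lowest in the neutrophil list, at -1.61 and -1.74.

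Of 4 myeloid gene lists, 3 were called lower in NHD13 and the list of maturing neutrophils was not. All 22 tested genes of granulocyte-monocyte progenitors lay below 0, with a median of -1.01, yet none passed by itself (camera adjusted p = 2.5e-05; adjusted p = 0.57 with an estimated correlation). Csf1r, the receptor of macrophage growth factor, measured -1.04 ± 0.48 (SE, adjusted p = 0.67), Plac8 measured -0.86, and Elane, the neutrophil elastase gene, -1.26. Without NHD13 replicate 2 the median was -0.12 and the call was lost, without NHD13 replicate 3 it was -1.78, and without both arrays numbered 2 it was -0.53. The genotypes overlapped in the list mean: wild type replicate 2 lay at -0.28 relative to the 6 arrays, under NHD13 replicates 1 (-0.13) and 3 (0.77). Monocyte, macrophage and dendritic cell genes fell as a list with a median of -0.69 over 14 members (camera adjusted p = 0.0039; adjusted p = 0.57 with an estimated correlation). The chemokine receptor gene Cx3cr1 measured -1.62 and H2-Ab1, of antigen presentation, -1.36; with the replicate block H2-Ab1 passed (adjusted p = 0.047). That list's call was lost without wild type replicate 3 (median -0.36), and the median was -1.38 without wild type replicate 2, -1.14 without NHD13 replicate 3, -0.36 without background correction, -0.46 without a detection filter and -1.36 with detection on all 6 arrays.

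Mast cell, basophil and eosinophil genes fell as a list with a median of -1.43 over 16 members (camera adjusted p = 0.00075; adjusted p = 0.57 with an estimated correlation). Fcer1a, the IgE receptor chain, was at least 6.20-fold lower with a wild type SD of 2.10 (adjusted p = 0.44), a bound of 14.3-fold without wild type replicate 2 and 3.72-fold without wild type replicate 3, and Il4 was at least 1.45-fold lower (adjusted p = 0.20) and passed over the list alone. Without NHD13 replicate 2 the list's median was -0.61 and without wild type replicate 3 it was -0.48, both still called. It was -0.68 without background correction, -0.45 without a detection filter and -0.95 with detection on all 6 arrays. Genes of maturing neutrophils were not called as a list (median -0.38, mean -0.11 over 20 members, adjusted p = 0.62), but were with the replicate block (adjusted p = 0.0077; 0.62 with an estimated correlation added). Their median was -1.44 without wild type replicate 2 and -1.49 without NHD13 replicate 3, both called, and 0.55 without NHD13 replicate 2, called in the other direction. Stfa1 and Stfa2, inhibitors of cathepsins, went against the list: Stfa1 was at least 13.5-fold higher and Stfa2 at least 1.95-fold higher (adjusted p = 0.22 each), and both passed over the list alone. Stfa1 varied between NHD13 arrays (SD 2.06 in log2), and its bound was 6.06-fold without NHD13 replicate 3 and 23.9-fold without NHD13 replicate 2.

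Lymphoid-priming and B progenitor genes fell as a list, 9 of 10 members below 0 with a median of -0.91 (camera adjusted p = 2.5e-05; adjusted p = 0.46 with an estimated correlation). Dntt, the terminal transferase of early lymphocytes, was below background on all NHD13 arrays and at least 3.63-fold lower (adjusted p = 0.031; 0.058 with the replicate block). Dntt passed in 5 of 16 alternatives that tested it. The list's median was -0.46 without wild type replicate 3, -1.46 without NHD13 replicate 3, -0.43 without background correction or without a filter, and -0.56 with detection on all 6 arrays. Genes of other cells that the sort could let through did not pass as lists. Mature B cell genes had a median of -0.20 over 6 members (adjusted p = 0.62), with H2-Ob at 0.47 and Jchain near background in both genotypes, and the median was -0.01 without NHD13 replicate 1 and -0.43 without NHD13 replicate 3. T and NK cell genes had a median of -0.31 over 5 members, with Cd27 at -1.27 and Cd8b1 at -0.44 (adjusted p = 0.054; 0.031 with the replicate block, and 0.55 with an estimated correlation added). Of 19 stromal, bone and endothelial genes 4 were tested, with a median of -0.68 (adjusted p = 0.28), with Vim at -1.23 and Igfbp4 at -0.90. In wild type cells Cd27, Cd8b1, Vim and Igfbp4 measured 11.7, 12.4, 11.4 and 12.3 in log2, against 12.8 for Kit. Signal this bright need not come from other cells. The T and NK and the stromal lists therefore do not measure how many such cells were let through.

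Genes of cell death showed no call. Over 7 pro-apoptotic members of the BCL2 family the median was 0.07 (adjusted p = 0.62), with Bak1 at 0.55 and Bcl2l11 at 0.21. Over 6 anti-apoptotic members it was -0.07 (mean -0.33, adjusted p = 0.18). Bcl2 itself measured 7.75 ± 0.77 in NHD13 and 9.51 ± 0.09 in wild type (log2, SD, n = 3), a difference of -1.76 that passed over the list alone but not over all genes (adjusted p = 0.20), and Bcl2l2 measured -0.16. Targets of p53 had a median of -0.01 over 24 members (adjusted p = 0.62), with Cdkn1a at -1.41 and Zmat3 detected on 3 wild type arrays and 1 NHD13 array.

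Cell cycle and repair genes lay slightly above 0. DNA replication and S phase genes had a median of 0.11, 20 of 25 above 0, with Ccne2 at 0.48 and Cdc6 at 0.37 (adjusted p = 0.0505; 0.042 with the replicate block, and 0.62 with an estimated correlation added). DNA damage repair genes had a median of 0.15, 22 of 27 above 0, with Fanci at 0.42 and Fancd2 at 0.35 (adjusted p = 0.063; 0.031 with the replicate block, and 0.55 with an estimated correlation added). Mitosis genes had a median of 0.09 over 17 members (adjusted p = 0.40), with Plk1 at 0.41 and Cdc20 at 0.25. Ribosomal protein genes had a median of -0.03 over 47 members (adjusted p = 0.21), with Rplp0 at 0.36 and Rps3a1 at -0.32.

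Immediate-early and heat shock genes fell as a list with a median of -0.29 over 21 members (camera adjusted p = 0.015; adjusted p = 0.57 with an estimated correlation). None of its members passed by itself, and the 2 of smallest p were Egr1 at -1.03 ± 0.24 (SE, adjusted p = 0.28) and Jun at -0.84 ± 0.21. The call was lost without NHD13 replicate 2 (median -0.09) and without wild type replicate 3 (median -0.14), and the median was -0.79 without NHD13 replicate 3 and -0.49 without wild type replicate 2. It was -0.17 both without background correction and without both arrays numbered 2, and -0.45 with array weights. Glycolysis and hypoxia genes fell as a list with a median of -0.31 over 17 members (camera adjusted p = 0.015; adjusted p = 0.46 with an estimated correlation). Ndrg1, a gene induced by low oxygen, fell 3.28-fold (adjusted p = 0.023), while the glycolytic genes Gapdh (0.02) and Ldha (0.04) stood near 0. That list's call was lost without wild type replicate 1 (median -0.07), and its median was -0.10 without NHD13 replicate 2, -0.18 without background correction, -0.08 without a filter, -0.07 with detection on all 6 arrays, -0.13 with averaged probes and -0.19 without both arrays numbered 2. Interferon response genes had a median of 0.23 over 22 members, with Oasl1 at 1.33 ± 0.20 (adjusted p = 0.068), which passed over the list alone and of which a dimmer probe passed over all probes (adjusted p = 0.035), and Isg15 at 0.86 (adjusted p = 0.054 for the list; 0.042 with the replicate block, and 0.55 with an estimated correlation added).

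Sex-linked genes were read gene by gene. Xist, expressed from the inactive X chromosome of females, and the Y-linked Eif2s3y were both detected on 6 of 6 arrays, with Xist between 9.46 and 10.93 and Eif2s3y between 6.29 and 7.95 in log2. Eif2s3y was highest on both arrays numbered 2, at 7.95 in wild type and 7.73 in NHD13, against 6.29 to 6.95 on the others. Xist was lowest on wild type replicate 2. Whether the share of males differed by replicate number was not tested. Xist differed between genotypes by 0.48 (adjusted p = 0.73), Eif2s3y by -0.18 (adjusted p = 0.92) and Uty by -0.19 (adjusted p = 0.79).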

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

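The alternative without both arrays numbered 2 was the only one chosen after the data were seen. The 50 called genes kept their sign in every alternative that tested them, but their number depended on the arrays and the model. Leaving out 1 array gave 1 to 61 genes (0 to 23 higher, 1 to 38 lower; 1 to 88 probes; 0% to 75% higher). Genes past the threshold were 24 without background correction (11 lower, 33 probes, 54.2% higher), 31 with the authors' processed values (18 lower), 20 lower without a detection filter, and 7 with detection on all 6 arrays (3 higher, 4 lower, 11 probes), where fewer genes were tested. Array weights gave 342 (132 higher, 210 lower, 579 probes), with weights from 0.35 for NHD13 replicate 3 to 5.02 for NHD13 replicate 1. The weighted NHD13 mean thus rests mostly on 1 pool, and the cause of that weight was not tested. The plain equal-variance test gave 0 genes and 0 probes (0 higher, 0 lower) with 662 genes at an unadjusted p under 0.05, where limma had 690. Without both arrays numbered 2, 16 passed (8 higher, 8 lower, 21 probes). The replicate block gave 56 (20 higher, 36 lower), 44 of them among the 50; it changed no other call than those given with it. Slide as a block was not run, since no label or header gives slides.

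Of the 24 lists, Hox, erythroid, haem, mast cell and lymphoid genes were called in all 17 alternatives with the preset correlation. With an estimated correlation, and with fry, 9 lists kept their medians but lost their calls: stem cell -0.26, erythroid 0.44, haem 0.36, granulocyte-monocyte -1.01, monocyte -0.69, mast cell -1.43, lymphoid -0.91, immediate-early -0.29 and glycolysis -0.31. The stem cell list also lost its call with detection on all 6 arrays (0.017) and array weights (-0.36). S phase genes were called without background correction (0.11), with median scaling (0.10), the authors' values (0.11), no filter (0.11), the block (0.11), trend and robust variance (0.11), array weights (0.18), offset 50 (0.11), averaged probes (0.11) and without both arrays numbered 2 (0.14). Interferon genes were called with median scaling (0.16), strict detection (0.31), the block (0.23), averaged probes (0.26) and without both arrays numbered 2 (0.28). T and NK genes were called with the block (-0.31), trend (-0.31) and weights (-0.31), repair genes with no filter (0.12) and the block (0.15), neutrophil genes with the block (-0.38) and ribosomal genes with trend (-0.032). For Hox cofactors, strict detection turned the set test from higher, not called, to lower, called (median -0.20), with fewer members tested. The strict filter dropped fallen stem cell members, such as Robo4 and Nkx2-3, and the risen Hoxb5, Pbx3 and Eya1. It cannot test their changes, and beyond this no cause was tested.

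Leaving out 1 array moved list medians over these ranges, with calls lost or gained on the way: granulocyte-monocyte -1.78 to -0.12, neutrophil -1.49 to 0.70, with a reversed call at 0.55 without NHD13 replicate 2, monocyte -1.38 to -0.36, T and NK -0.51 to -0.10, S phase 0.078 to 0.15, repair 0.081 to 0.21, interferon 0.12 to 0.32, immediate-early -0.79 to -0.090 and glycolysis -0.45 to -0.074. The lists called in none of these fits ranged from -0.28 to 0.37 for megakaryocyte, -0.43 to -0.012 for mature B, -0.91 to -0.41 for stromal, -0.12 to -0.015 for Hox cofactor, -0.042 to 0.17 for pro-apoptotic, -0.17 to -0.029 for anti-apoptotic, -0.051 to 0.062 for p53, -0.0097 to 0.18 for mitosis and -0.042 to -0.017 for ribosomal genes. Among results for single genes, 938 of the alternatives' values kept their side of the threshold, 118 lost the call, 21 gained it and none was called in the other direction. Uncalled values could change sign, as for Nup98, which ranged from -0.03 to 0.19. Median scaling moved the median of all genes from 0.03 to -0.04. Signal over background limits 24 of the 50 genes to a bound, and their size follows the background correction: the Hox median was 0.65 without it and 0.27 without a filter, which adds undetected members. The filter itself had let in Hox genes detected on the NHD13 arrays alone, such as Hoxc6.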

Other observations

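The tests on regrouped arrays, on granulocyte-monocyte genes, on stromal cells, on the stem cell list and on the number of Hox clusters were chosen after the results were seen, and those on background and on neighbouring lower genes were not. For the single array, the make-up of the pools, the stromal cells and the stem cell list, the rule for reading the value was also widened to an undecided outcome after the value was seen. The genes in this part were chosen after their values were seen. Epha3, an ephrin receptor gene, was below background on all wild type arrays and at least 5.63-fold higher (adjusted p = 0.12), or 3.64-fold without NHD13 replicate 3. Cstdc4, a relative of Stfa1 and Stfa2, was at least 2.70-fold higher (adjusted p = 0.48), or 1.47-fold without NHD13 replicate 3.

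With the replicate block, 12 further genes were called, among them 2 nucleotide receptors that went opposite ways: P2ry1 measured 1.62 (adjusted p = 0.15 without the block) and P2ry14 measured -1.43 (adjusted p = 0.052 without it). Hif3a, of the hypoxia response, measured 1.72, Mt2, a metallothionein gene, 1.23 and Cavin2, a caveolar protein gene, was detected on 1 of 3 NHD13 arrays. The genes called without the block alone were Bex4, Dntt, Fam110b, Igf2bp3, Rgl1 and Rgs1.

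The 50 called genes arose from the real grouping of the 6 arrays; of the 10 splits into 3 and 3, 1 gave as many, the real one, and the highest other count was 0 genes and 1 probe. The 3 other splits that part all pairs gave 0 genes each. These are too few splits for a share under 0.05. The split that set wild type replicates 1 and 3 and NHD13 replicate 3 against the rest had 4282 probes at an unadjusted p under 0.05, against 1269 for the real one, which points to a structure of the samples other than genotype. Those 3 arrays also had the highest means of the granulocyte-monocyte progenitor list, at 0.91, 0.88 and 0.77 relative to the 6 arrays. Wild type replicate 2 and NHD13 replicates 1 and 2 lay at -0.28, -0.13 and -2.16.

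Hox genes were higher in NHD13. A single altered locus that holds them would put them in 1 cluster, but the 8 called genes lay in 4. This does not cover a locus that acts on genes elsewhere. For higher background on the NHD13 arrays, the prediction was that probes would appear there more than vanish. Instead, 79 probes were detected on all NHD13 and no wild type arrays against 110 of the converse, a ratio of 0.718. Detection is judged against each array's own negative controls, which a higher background would raise too, so this ratio cannot decide. A response to the fusion protein, which the genotype names, stays open as a hypothesis and was not tested; so does cross-hybridisation with the transgene's own Hox sequence, which needs probe sequences.

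Granulocyte-monocyte progenitor genes were lower in NHD13 with a median of -1.01. Whether the shift rests on 1 array, NHD13 replicate 2, stays open. Without it the median was -0.12, but this leaves its low partner, wild type replicate 2, in the comparison, and without both arrays numbered 2 the median was -0.53, still called. The list means of the 3 pairs differed by -1.04, -1.88 and -0.11. Uneven make-up of the pools cannot be told apart from an effect of genotype: the mean of the 3 same-number differences was -1.01 with a standard error of 0.51, a ratio of -1.98, and 3 pairs are too few. A change of these progenitors with the transgene stays open.

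Genes lower in NHD13 included Fkbp9, Ppic, Mmp2 and Robo4, some of which are also expressed outside blood. A part played by stromal cells in the wild type pools cannot be told apart from an effect of genotype. Of Col1a1, Col1a2, Col3a1, Sparc and Cxcl12, 0 were detected on all 3 wild type arrays. Col1a2 was detected on 2 wild type and 0 NHD13 arrays, the direction such cells would give, but Cxcl12 on 0 wild type arrays and 1 NHD13 array, the other direction. The level that a share of such cells would need is not known from other probes. Col1a1, Col3a1 and Sparc were detected on 0 arrays, and the sort for Kit should remove stromal cells that lack it. As a set, endothelial genes were tested only within the list of stromal, bone and endothelial genes, of which 4 were tested with a median of -0.68 (adjusted p = 0.28), and this does not settle their part. A single narrow locus that holds most of these genes is argued against by gene order in the RefSeq table. There, 6.67% of the 30 genes that could be placed, of 32 called lower, had another at most 10 genes away, the pair Bex4 and Tceal8. This does not cover a locus behind a few of the genes, a wider segment, or a locus that acts on genes elsewhere. An evenly lower share of stem and multipotent cells could account for part: the whole list's median was -0.26, and 9 of its 23 members lay above 0. A bootstrap interval from -1.04 to 0.05 came from resampling the list's genes and holds no spread between pools. The list does not settle it. Regulation of these genes by the transgene stays open and was not tested.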
